A study of Mus musculus with 6 samples.

How the data were processed

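LSK cells from 3 wild-type and 3 NIKaly/aly samples were profiled on Agilent mouse oligonucleotide arrays, 1 Cy3-labelled sample per array. RNA was extracted with TRIzol, amplified and labelled with a low-input kit, per the labels' protocols. Spot intensity was extracted by the submitters with Agilent Feature Extraction 10.7.3.1, per the file headers, which also give the protocol and the mm9 build for probe positions. The deposited intensity values include a processed signal per spot, background-subtracted with low values replaced by a surrogate, and flags for outliers, saturation and signal well above background. The authors' deposited series table holds 1 column per array. In it, each value equals the processed signal divided by the array's median over the 59305 non-control spots, so each column's median is 1. It therefore gives what median scaling gives, and it was used as an alternative.

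Choices of groups, tests, thresholds, gene lists and alternatives were made before the data were examined, except where stated. The log2 of the processed signal was set relative to each array's 75th percentile over non-control spots. Control spots and spots with an outlier flag were left out. No spot was saturated. Spots of 1 probe were averaged, which left 55681 probes with 34821 gene names. Probes were tested if well above background on at least 3 of the 6 arrays, whatever the group, which 21239 were; 22 of these lacked a value on an array and were left out. Of several probes with 1 gene name, for 4070 genes, the probe with the highest mean over all arrays was kept, leaving 15682 genes. At most 45.6% of the spots of an array were well above background, so the percentile over the 15818 probes well above background on all 6 arrays was added as an alternative after the data were seen. Gene names are those of the files. Through a RefSeq gene table, 27503 probes matched a current symbol by accession, 3554 by symbol and 404 by a synonym, and 24220 had no match and kept the file's name. That table's coordinates were not used. List members were matched by the file's gene name, then by the current symbol.

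Genotypes were compared with limma 3.58.1 in R 4.3.3, with lmFit and eBayes with an intensity trend on 4 residual degrees of freedom, two-sided, and Benjamini-Hochberg adjustment at 0.05. Genotype was the only term, since the labels state no test and no sample number is shared by both genotypes. A lenient count took genes at least 2-fold apart with an unadjusted p under 0.05. Gene lists with at least 5 tested genes were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation, and with fry, which tests whether a list's genes move on balance 1 way and compares it with no other genes. With an estimated correlation camera uses the residual degrees of freedom, 4 here and 2 with the pair block described below. With the preset one it uses far more. A call lost with the estimate thus need not mean that a list's genes vary together. The 27 tested lists cover stem and progenitor genes (hematopoietic stem cell, lymphoid-primed, granulocyte-monocyte, megakaryocyte-erythroid), NF-kB pathway components with canonical and alternative targets, cell-cycle and cell-cycle inhibitor genes, apoptosis, interferon response, niche adhesion and homing, class II antigen presentation, oxidative phosphorylation, glycolysis, ribosomal proteins, immediate-early and heat-shock genes, and markers of T, B, plasma and NK cells, mature neutrophils, macrophages and dendritic cells, eosinophils with basophils and mast cells, erythroblasts, and endothelial and stromal cells. Some genes stand in several lists.

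The rule for named genes took Map3k14, the 12 largest rises and 12 largest falls past the threshold with non-overlapping groups, up to 4 members of each list with the smallest unadjusted p, and the sex check genes. As no gene passed, the 12 were filled with the smallest unadjusted p among genes at least 2-fold apart with non-overlapping groups. Entries with certain kinds of identifier in place of a gene name were counted and not named. They were 14 of 63 rises and 28 of 88 falls at least 2-fold apart with non-overlapping groups. U30243, U41438, S60874 and HQ446714 also lack a gene name, but their kind of identifier was not excluded. Which immunoglobulin entries are named thus depends on the form of the identifier. Values are printed for 4 members of each list called with or without the block and for up to 2 of each other list of progenitors or pathways, numbers that were decided after the values were seen. A group with no array well above background for a gene is given as a bound, the other group's mean against, per array, the higher of the lowest signal well above background and the probe's own signal.

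All 6 arrays came from 1 slide and 1 scan. Slide row 1 holds samples 1 to 4 and row 2 holds samples 5 and 6, so row was fitted as a block. Array column lies within genotype, and was fitted as a random block with duplicateCorrelation, added after the data were seen. After the data were seen, consecutive sample numbers were taken as a pair: deviations from the genotype mean correlated at 0.74, 0.69 and 0.60 over genes in the 3 pairs. The labels do not say what consecutive samples share. Fits without samples 1 and 2 were also added after the data were seen. Alternatives chosen beforehand were quantile normalization, median scaling, normexp background correction with an offset of 50, no filter and a filter on all 6 arrays, eBayes without the trend and robust, array weights, all probes or their mean, stricter and looser thresholds, and leaving out each array. Camera took neither the eBayes settings nor the random block, so for lists those fits repeat the main result. The authors' table repeats median scaling.

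The fits were tested on simulated data for this comparison, with the 15682 genes' means and spreads and 50 changed genes at each size of change. With pairs differing as they did here, the fit without a block called 0% of changes of 1 log2 unit, 48% of 2, 78% of 3 and 84% of 4, with 2 false calls. The pair block called 26%, 68%, 82% and 84%, with 1 false call. Simulated genes varied independently, so the simulation says nothing about genes that vary together in a list. The many planted changes also loosen the Benjamini-Hochberg cutoff. The shares called are therefore not the power for single genes in the real arrays.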

Results

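Transcript levels were measured in LSK cells, the lineage-negative, Sca-1-positive and c-Kit-positive fraction that holds mouse hematopoietic stem cells and multipotent progenitors. The cells were sorted from wild-type mice and from NIKaly/aly mice. NIK, encoded by Map3k14, is the kinase that starts alternative NF-kB signalling, and the aly allele is a point mutation that disables it. The comparison asks how the defective kinase changes gene expression in this population. Each genotype gave 3 samples, hybridised singly to 6 one-colour arrays on 1 slide. The wild-type samples carry the numbers 1, 3 and 5 and the NIKaly/aly samples the numbers 2, 4 and 6. Between 33.1% (wild type 1) and 45.6% (wild type 3) of the 59305 non-control spots were well above background. The quality summary in the file headers marked wild type 1 and NIKaly/aly 6 for evaluation and the other arrays as in range. The 75th percentile of the signal was 47.0, 225 and 80.2 in wild type 1, 3 and 5, and 126, 201 and 50.8 in NIKaly/aly 2, 4 and 6. The number of arrays limits the precision. Nothing in the labels says that the samples came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

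Arrays with consecutive sample numbers, 1 from each genotype, resembled each other more than arrays of 1 genotype did. Over the 15682 tested genes, Pearson's r was 0.975 to 0.989 for samples 1 and 2, 3 and 4, and 5 and 6. It was 0.937 to 0.975 between samples of 1 genotype and 0.929 to 0.970 between the other samples. These correlations are across genes, which are not independent replicates. The first principal component held 59.5% of the variance and set wild type 1 and NIKaly/aly 2 apart from the other 4 arrays. The beta-globin gene Hbb-b1 was at 7.61 and 6.51 log2 units above the array's 75th percentile on these arrays and between 2.47 and 3.18 on the others. Genes abundant in mature neutrophils were bright on all 6 arrays, S100a9 at 9.32 to 11.84 and Camp at 7.19 to 10.18. Signal of mature-cell genes was thus not confined to samples 1 and 2. Because consecutive samples resembled each other, each comparison was also fitted with these pairs as a block, a choice made after the data were seen.

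**Figure D1:**
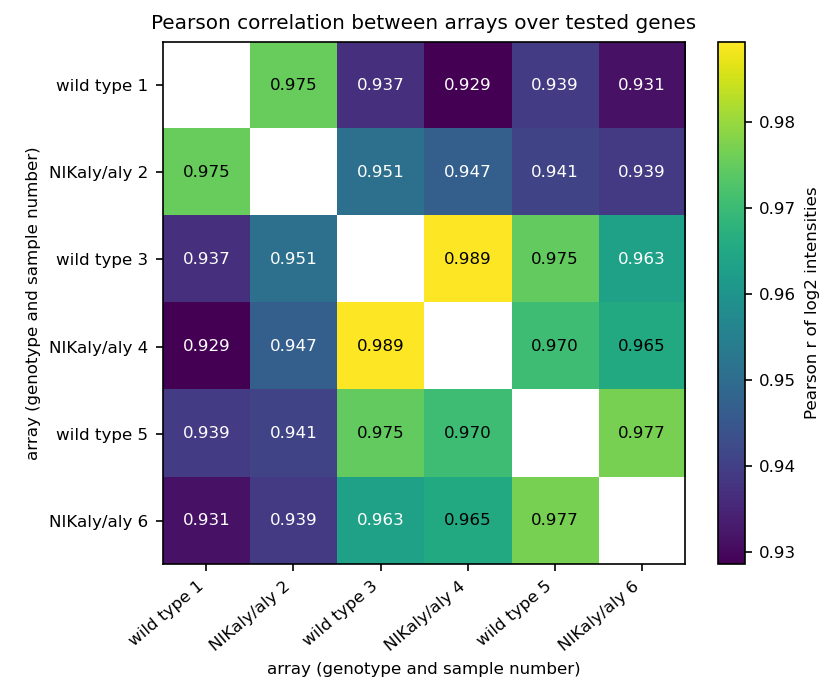
Pearson correlation of log2 intensities over 15682 genes for each pair of the 6 arrays, named on both axes by genotype and sample number, with lighter colour for higher r. For each array the highest value is the one with its consecutive number, from 0.975 to 0.989.

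Map3k14, the gene that carries the mutation, was measured in every sample by 2 probes, both well above background on all 6 arrays. Its brighter probe, at chromosome 11, 103081249 to 103081308 on the mm9 build, read 0.73, 2.54 and 2.06 in wild type 1, 3 and 5. It read 1.60, 2.53 and 2.14 in NIKaly/aly 2, 4 and 6, in log2 units above the array's 75th percentile. The difference of 0.31 ± 0.48 (SE) was smaller than the spread between samples (limma, Benjamini-Hochberg adjusted p = 0.99998). It was -0.21 without wild type 1 and 0.04 without samples 1 and 2. It was 0.43 within slide row 1 (samples 1 to 4) and 0.08 in row 2 (samples 5 and 6). The second probe differed by 0.25. The allele is a point mutation, so transcript level does not check the genotype labels. In the sex check, Xist was not well above background on any array by either of its 2 probes, while Ddx3y and Eif2s3y were well above background on all 6. Ddx3y lay between 0.41 and 2.07 and Eif2s3y between 0.19 and 2.08. The Kdm5d probe was well above background on 2 arrays, and the brighter Uty probe on 4.

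Genes that read higher in NIKaly/aly included the secreted ribonuclease gene Rnase4 (log2 difference 2.31 ± 0.43, SE, n = 3 per genotype; limma, Benjamini-Hochberg adjusted p = 0.99998), the peptide-amidating enzyme gene Pam (2.73) and Batf2 (1.24), which encodes a basic leucine zipper transcription factor. Genes that read lower included the mitochondrial import receptor gene Tomm22 (-2.69 ± 0.47; limma, adjusted p = 0.99998), Ms4a6c (-2.35) and the integrin gene Itga9 (-2.21). Entries for immunoglobulin kappa or light chain variable regions also read lower: U30243 (-3.84 ± 0.70), S60874 (-3.13) and HQ446714 (-3.10). A kappa chain entry that the naming rule left out for the form of its identifier read higher (2.92). It was well above background on 0 of 3 wild-type and 3 of 3 NIKaly/aly arrays. No gene passed the adjustment in limma, and the smallest adjusted p was 0.99998. At an unadjusted p under 0.05 there were 208 genes (1.33%). Groups did not overlap for 716 genes (4.57%), where chance gives 10% for exchangeable arrays. Consecutive samples resembled each other, which makes non-overlap rarer without any change. At a difference of at least 2-fold with an unadjusted p under 0.05 there were 139 genes, 56 higher and 83 lower in NIKaly/aly.

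The genes named here are the 12 in each direction with the smallest unadjusted p among those at least 2-fold apart with non-overlapping groups that the naming rule admits. None passed the adjustment. Other genes that read higher were Adat2 (1.62), a subunit of a transfer RNA deaminase, Aspa (2.71), Raver2 (1.39), Slco2a1 (1.90), a prostaglandin transporter, and Bex2 (1.91). Fam134b, now Retreg1, a receptor for autophagy of the endoplasmic reticulum, differed by 1.08. Nnt, which encodes a mitochondrial transhydrogenase, differed by 1.01. Ttc39a and Asb4 were not well above background on any wild-type array and were at least 3.56-fold and at least 2.42-fold higher in NIKaly/aly (adjusted p = 0.99998 in limma). These bounds set the brighter group's mean against the lowest signal well above background. Rnase4, Pam, Aspa, Slco2a1 and Bex2 were well above background on 1 of 3 wild-type arrays, and Raver2 on 2. With normexp background correction 14 of the 24 differences were smaller by over 1.5 times, 13 of them by over 2 times. These were Rnase4 (0.77), Pam (0.79), Aspa (0.89), Slco2a1 (0.54), Bex2 (0.52), Raver2 (0.63), Itga9 (-0.69), U30243 (-1.51), S60874 (-1.33), HQ446714 (-1.34) and the 3 genes given as bounds, and by less Unc5a (-1.55). Those 3 were Ttc39a (0.63), Asb4 (0.54) and U41438 (-1.13), each then smaller than its bound. The offset of 50 added with normexp was near the 75th percentile of wild type 1 (47.0) and NIKaly/aly 6 (50.8). It draws dim signals together, so shrinkage of dim genes was fixed in advance and does not test them. With the mean of a gene's probes Nnt (0.40), Raver2 (0.69) and Steap3 (-0.77) were smaller by over 2 times. Array weights made 1 of the 24 smaller by over 1.5 times, and so did leaving out samples 1 and 2. Leaving out 1 array moved none of the 24 by over 1.5 times. The 24 were chosen from these same arrays for non-overlapping groups and a small p, so this does not test them.

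Other genes that read lower were Rps4y2 (-1.90), now Rps4l, Abhd14b (-1.71), Steap3 (-1.97), a ferrireductase, Unc5a (-2.70), a netrin receptor, and Heatr5a (-1.06). The light chain entry U41438 was not well above background on any NIKaly/aly array and was at least 5.16-fold lower there. U30243, S60874, HQ446714 and Itga9 were well above background on 1 of 3 NIKaly/aly arrays, and Unc5a on 2. The probes of Steap3, Raver2 and Nnt differed in direction, the dimmer ones reading 0.43, -0.01 and -0.21. With the pairs as a block, 2 genes passed in limma. They were U30243 (adjusted p = 0.017), measured at chromosome 6, 68071630 to 68071689 on mm9, and a probe without a gene name that read higher. Over all alternatives in limma, the adjusted p of U30243 was 0.0011 to 0.99998. The lowest came with array column as a random block, where a negative correlation within a genotype shrinks the error. With median scaling the adjusted p of U30243 in limma was 0.0019. The unnamed probe lies outside the naming rule and was noted after its value was seen. At an unadjusted p under 0.05 there were then 1153 genes (7.35%), and at an adjusted p under 0.1 there were 15 higher and 21 lower. At least 2-fold with an unadjusted p under 0.05 were 255 genes, 91 higher and 164 lower. The median residual SD was 0.50 without the block and 0.22 with it. Tomm22, U30243, U41438 and HQ446714 passed with median scaling, where 10 genes did, and Tomm22, U30243 and Rps4y2 with array weights, where 5 did. Within slide row 1, no gene passed and 90 were at least 2-fold apart with an unadjusted p under 0.05; row 2 holds 1 array of each genotype.

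Granulocyte-monocyte progenitor genes fell in NIKaly/aly as a list (median -0.38, 22 tested genes; camera in limma, adjusted p = 4.2e-05). The list's adjusted p = 0.945 with an estimated correlation, which was 0.41, and 0.507 with a correlation estimated with the block. Of its members, 20 read lower and 2 higher, and 14 were lower in all 3 pairs. Csf1r, the receptor for macrophage colony-stimulating factor, differed by -1.17 ± 0.33 (SE) and Irf8, a transcription factor of the monocyte lineage, by -1.22 ± 0.37. Cebpa, a transcription factor needed for granulocyte-monocyte progenitors, differed by -0.69 ± 0.36, and Mpo, which encodes myeloperoxidase, by -0.72 ± 0.51. None of the 22 passed, whether over all genes or adjusted over the list alone. With the pairs as a block, 7 passed adjusted over the list alone, all lower. Markers of other myeloid cells also read lower: 12 of 13 of macrophages and dendritic cells (median -0.31), 17 of 20 of mature neutrophils (-0.16) and 14 of 18 of eosinophils, basophils and mast cells (-0.20). These 3 lists did not pass in camera (adjusted p = 0.075, 0.665 and 0.096) and were called lower with the block, none with an estimated correlation. The call was lost without wild type 1 (median -0.03) and without NIKaly/aly 4 (median -0.09), and the median was -0.84 without NIKaly/aly 2 and -0.79 without wild type 3. The median was -0.50, -0.29 and -0.32 in the 3 pairs, -0.38 within slide row 1 and -0.28 without samples 1 and 2.

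**Figure D2:**
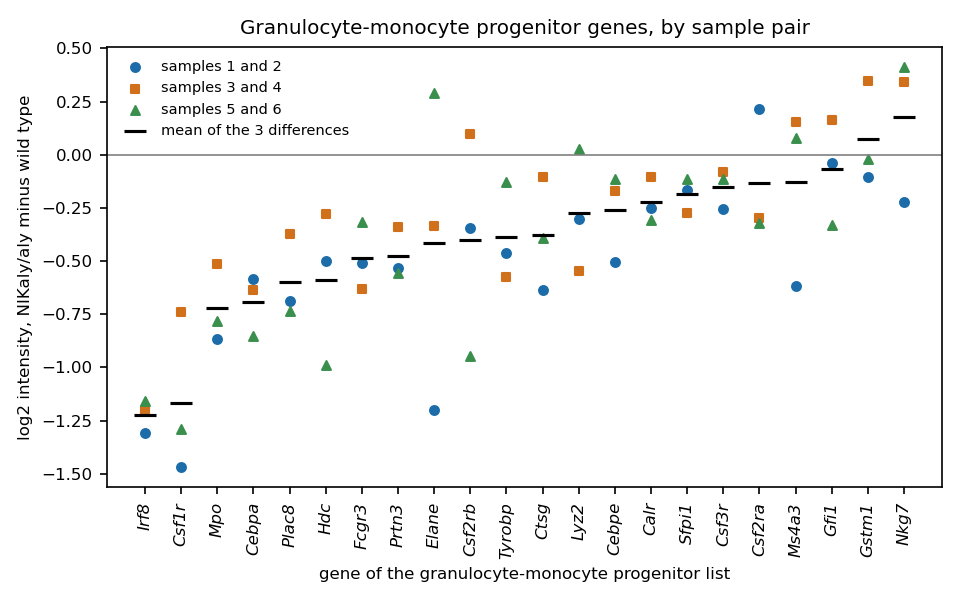
Log2 intensity in the NIKaly/aly sample minus that in the wild-type sample of the consecutive number (y axis) for each of the 22 tested granulocyte-monocyte progenitor genes (x axis), with 1 symbol per sample pair and a bar for the mean of the 3 differences. The bar lies below 0 for 20 genes, and all 3 symbols do for 14.

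B cell markers, which a lineage-negative sort is meant to leave out, fell as a list (median -0.75, 15 genes, adjusted p = 1.7e-04 by camera in limma), with 14 lower and 1 higher. The list's adjusted p = 0.945 with an estimated correlation, which was 0.65. Igj, the immunoglobulin joining chain, differed by -3.01 ± 1.52, Faim3 by -2.73 ± 1.72, Blnk by -0.67 ± 0.52 and Cd79a, a subunit of the B cell receptor, by -1.36 ± 1.20. The median was -0.93, -1.84 and 0.16 in the 3 pairs. With the block, 2 members passed adjusted over the list alone, Faim3 and Cd79a, against 0 without it. The call was lost without wild type 1 (median -0.11) and without NIKaly/aly 4 (median -0.03), and the median was -1.45 without NIKaly/aly 2 and -1.41 without wild type 3. Igj was -1.06 without NIKaly/aly 6 and -4.46 without NIKaly/aly 2. Without NIKaly/aly 4, Faim3 was -0.84, Blnk -0.063 and Cd79a -0.15, against -4.27, -1.01 and -2.29 without NIKaly/aly 2. Igj and Faim3 were well above background on 2 of 3 NIKaly/aly arrays. Plasma cell markers had a median of -0.30 (camera adjusted p = 0.096, and 0.945 with an estimated correlation), and -0.55 to -0.014 leaving out 1 array. They were called lower in 6 of 27 alternatives (adjusted p = 1.6e-04 with median scaling, 0.0069 with normexp; 1.6e-04 to 0.998 over all), among them without wild type 3 (-0.41) and without NIKaly/aly 6 (-0.49). The 6 count both median scaling and the authors' table, which repeats it.

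Interferon response genes fell as a list (median -0.19, 36 genes, adjusted p = 8.8e-04 by camera in limma), with 26 lower and 10 higher. The list's adjusted p = 0.945 with an estimated correlation, which was 0.17. The antiviral genes Oasl1 (-0.78 ± 0.29) and Rsad2 (-0.77 ± 0.29) and the deconjugating enzyme gene Usp18 (-1.06 ± 0.41) read lower, while the chemokine gene Cxcl10 read higher (0.87 ± 0.34; its dimmer probe read -0.05). With the block, 9 members passed adjusted over the list alone, 7 of them lower, against 0 without it. The median was -0.051, -0.29 and -0.23 in the 3 pairs and -0.20 within slide row 1. The call was lost without wild type 3 (median -0.22), and the median was -0.41 without NIKaly/aly 2, -0.36 without wild type 5 and -0.11 without NIKaly/aly 6.

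Cell-cycle inhibitor genes rose as a list (median 0.19, 23 genes; camera in limma, adjusted p = 0.0040), with 17 higher and 6 lower and no member past the threshold adjusted over the list alone, with or without the block. The list's adjusted p = 0.635 with an estimated correlation. That estimate, 0.0061, was below the preset 0.01, so correlation among its genes does not explain the lost call. The fewer degrees of freedom used with an estimate do: camera's unadjusted p rose from 5.9e-04 to 0.024. Foxo3 differed by 0.41 ± 0.24, Rbl1, a relative of the retinoblastoma protein, by 0.42 ± 0.28, Btg3 by 0.59 ± 0.40 and Gadd45b by 0.44 ± 0.32. The median was 0.18, 0.25 and 0.073 in the 3 pairs. The call was lost without wild type 1 (median 0.16), wild type 3 (0.09) or NIKaly/aly 6 (0.16). Cell-cycle genes had a median of 0.029 (19 higher, 15 lower; camera adjusted p = 0.665), with Nusap1 at 0.45 ± 0.28 and Cenpe at 0.29 ± 0.35.

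The NF-kB lists did not pass camera's threshold with all 6 arrays. Pathway components had a median of 0.025 (18 higher, 14 lower; adjusted p = 0.871), with the receptor gene Tnfrsf11a at 1.27 ± 0.55 (well above background on 1 of 3 wild-type arrays; 0.36, 0.64 and 2.82 in the 3 pairs, 0.82 without wild type 5 and 0.40 with normexp) and the lymphotoxin gene Ltb at -0.58 ± 0.34. Canonical targets had a median of 0.096 (19 higher, 12 lower, camera adjusted p = 0.217, and 0.976 with an estimated correlation), with Cxcl10 as above and Irf1 at 0.44 ± 0.29. The canonical targets were called higher without NIKaly/aly 4 (median 0.38, adjusted p = 0.0019) and without wild type 5 (0.14, adjusted p = 0.0059), in 2 of 27 alternatives (0.0019 to 0.998 over all), and had a median of -0.085 without wild type 3 and -0.039 without NIKaly/aly 6. With the block, 4 of them passed adjusted over the list alone, all higher. Alternative targets had a median of -0.17 (3 higher, 10 lower; adjusted p = 0.164), with the survival gene Bcl2l1 at -0.34 ± 0.35, the chemokine gene Cxcl12 at -1.09 ± 1.14, the chemokine receptor gene Ccr7 at -0.85 ± 1.19 and Ccl19 at -0.37 ± 0.55. Cxcl12 and Ccl19 were well above background on 2 of 3 wild-type and 1 of 3 NIKaly/aly arrays. With the pairs as a block the alternative targets were called lower (camera adjusted p = 0.048), and not with an estimated correlation (adjusted p = 0.507). They were also called lower without wild type 3 (median -0.50) and without NIKaly/aly 6 (-0.26), and the median was 0.13 without NIKaly/aly 4 (adjusted p from 0.0038 to 0.998 over all alternatives).

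Hematopoietic stem cell genes had a median of 0.057 (21 higher, 15 lower; camera adjusted p = 0.766), with the endothelial protein C receptor gene Procr at 0.78 ± 0.28 and Txnip at -0.75 ± 0.29. With the block, 3 members passed adjusted over the list alone, Procr higher and Vwf and Ly6a lower, against 0 without it; the last 2 were named after their values were seen. Lymphoid-primed progenitor genes had a median of -0.14 (15 of 23 lower, camera adjusted p = 0.095, and 0.945 with an estimated correlation), with Notch1 at -0.64 ± 0.42. They were called lower in 10 of 27 alternatives, among them median scaling (adjusted p = 0.025), normexp (0.011), no filter (0.0044), array weights (2.1e-06) and without samples 1 and 2 (0.021), against 2.1e-06 to 0.998 over all. The 10 count both median scaling and the authors' table, which repeats it. Leaving out 1 array gave -0.29 (without wild type 5) to -0.025 (without NIKaly/aly 4), with calls without wild type 1 (-0.087), wild type 5 and NIKaly/aly 6 (-0.13). Megakaryocyte-erythroid genes had a median of -0.094 (adjusted p = 0.871), with Car2 at 0.48 ± 0.37 and Tfrc at 0.23 ± 0.26. Niche adhesion and homing genes had a median of -0.094 (20 of 30 lower; adjusted p = 0.095). Itga9 was their 1 member that passed adjusted over the list alone; with the block Itgb7, named after its value was seen, passed as well, also lower. In this list the integrin gene Itgb1 differed by 0.55 ± 0.25. Apoptosis genes had a median of -0.017 and camera placed them up (adjusted p = 0.990), with Tnfrsf10b at 0.62 ± 0.34 and Bmf at -0.41 ± 0.34. Class II antigen presentation genes had a median of -0.032 and a mean of 0.072 (adjusted p = 0.990), with Cd80 at -0.49 ± 0.30 and H2-Aa at 0.92 ± 0.81. Oxidative phosphorylation genes had a median of 0.016 (adjusted p = 0.871; Sdha 0.27 ± 0.31, Sdhc 0.21 ± 0.38). Glycolysis genes had a median of -0.075 and a mean of 0.0063, and camera placed them up (adjusted p = 0.766; Aldoc 0.57 ± 0.27, Ldhb 0.45 ± 0.31). Ribosomal protein genes had a median of -0.0022, and camera placed them up (adjusted p = 0.997; Rpl5 0.14 ± 0.41, Rpl7 0.14 ± 0.45). Of the 27 lists tested, 4 were called, 3 lower and 1 higher, and none with an estimated correlation or by fry.

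**Figure D3:**
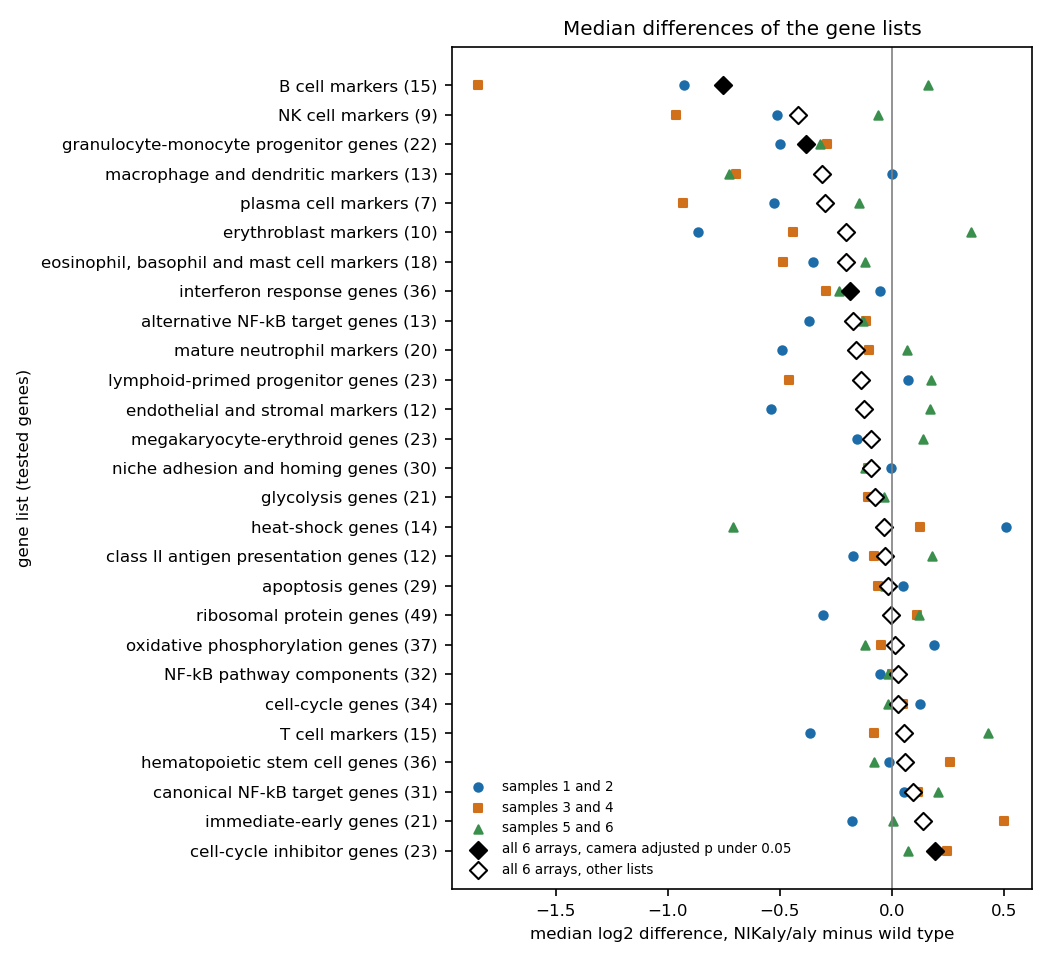
Median log2 difference, NIKaly/aly minus wild type (x axis), of each of the 27 gene lists (y axis, tested genes in parentheses), with diamonds for all 6 arrays, filled for the 4 lists called by camera, and 1 small symbol per sample pair. The granulocyte-monocyte list lies below 0 in all 3 pairs, and the B cell list in samples 1 and 2 and 3 and 4 but not in 5 and 6.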

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

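The pair block alone and with other settings, the percentile over detected probes, the array column and the fits without samples 1 and 2 were chosen after the data were seen. Low signal limits the reading of dim genes, as 33.1% to 45.6% of spots per array were well above background. In limma, no gene passed with quantile normalization, the filter on all 6 arrays, either other eBayes, all probes, probe means, the slide row block, the percentile over detected probes or without samples 1 and 2. At an unadjusted p under 0.05 these gave, in that order, 274, 133, 234 (no trend) and 205 (robust), 248, 214, 252, 249 and 327 genes. The number passing was 10 with median scaling and with the authors' deposited table (1 higher, 9 lower), 1 with normexp, 2 without the filter, 5 with array weights, 2 with the pair block, 1 with the pair block and quantile normalization, and 0 to 1 leaving out 1 array, the 1 without wild type 3. With array column as a random block it was 1379 (749 higher, 630 lower), where the consensus correlation was -0.875 and columns hold at most 2 arrays, of 1 genotype and different pairs. Genes at least 2-fold apart with an unadjusted p under 0.05 were 42 with normexp, 251 without the filter, 57 with the filter on all 6 arrays, 244 with array weights, 255 with the pair block, 245 with the pair block and quantile normalization, and 562 with array column. Lists called were 9 with median scaling and with the authors' table, 10 without the filter, 14 with array weights, 9 with the pair block, 10 with the pair block and quantile normalization, 8 without samples 1 and 2, and 4 to 14 leaving out 1 array. They were 0 with an estimated correlation and 0 by fry, in each case with and without the pair block. Over all alternatives, the adjusted p ranged from 3.4e-11 to 0.998 for the granulocyte-monocyte list, from 1.9e-16 to 0.998 for B cell markers, from 2.4e-06 to 0.998 for interferon response genes, from 3.9e-04 to 0.998 for cell-cycle inhibitors, from 0.0038 to 0.998 for alternative and 0.0019 to 0.998 for canonical NF-kB targets, from 2.1e-06 to 0.998 for lymphoid-primed genes and from 1.6e-04 to 0.998 for plasma cell markers, in camera or fry. Leaving out 1 array called these lists that all 6 arrays did not, with the median in parentheses. Without wild type 1, lymphoid-primed (-0.087), cell-cycle (0.26), class II antigen presentation (0.25), oxidative phosphorylation (0.35), glycolysis (0.29), ribosomal protein (0.37), erythroblast (0.76). Without NIKaly/aly 2, hematopoietic stem cell (0.069), megakaryocyte-erythroid (-0.42), cell-cycle (-0.26), oxidative phosphorylation (-0.36), immediate-early (0.24), NK cell (-0.79), macrophage and dendritic (-0.75), eosinophil, basophil and mast cell (-0.81), erythroblast (-1.41). Without wild type 3, alternative NF-kB target (-0.50), niche adhesion and homing (-0.21), ribosomal protein (-0.25), plasma cell (-0.41), NK cell (-0.82), neutrophil (-0.88), macrophage and dendritic (-0.77), eosinophil, basophil and mast cell (-0.97). Without NIKaly/aly 4, canonical NF-kB target (0.38), neutrophil (0.55). Without wild type 5, lymphoid-primed (-0.29), canonical NF-kB target (0.14), immediate-early (0.30), heat-shock (0.14). Without NIKaly/aly 6, lymphoid-primed (-0.13), alternative NF-kB target (-0.26), cell-cycle (0.18), niche adhesion and homing (-0.13), oxidative phosphorylation (0.29), plasma cell (-0.49), NK cell (-0.58), neutrophil (-0.41), macrophage and dendritic (-0.48), eosinophil, basophil and mast cell (-0.54), endothelial and stromal (-0.22). Of the lists not called with all 6 arrays, other alternatives called these. With quantile normalization, ribosomal protein (0.049). With median scaling, lymphoid-primed (-0.039), plasma cell (-0.20), NK cell (-0.32), macrophage and dendritic (-0.21), eosinophil, basophil and mast cell (-0.10). With normexp, lymphoid-primed (-0.073), plasma cell (-0.088). With no filter, lymphoid-primed (-0.14), NK cell (-0.46), macrophage and dendritic (-0.28), eosinophil, basophil and mast cell (-0.20), endothelial and stromal (-0.13), all lower, and, higher, the 6 sex-linked check genes (0.33, adjusted p = 0.028), which had too few genes for a test in every other fit. With array weights, hematopoietic stem cell (0.16), lymphoid-primed (-0.33), alternative NF-kB target (-0.23), niche adhesion and homing (-0.17), immediate-early (0.33), plasma cell (-0.66), NK cell (-0.86), neutrophil (-0.49), macrophage and dendritic (-0.90), eosinophil, basophil and mast cell (-0.63). With probe means, lymphoid-primed (-0.16). With samples 1 and 2 left out, lymphoid-primed (-0.31), ribosomal protein (0.13), immediate-early (0.30), macrophage and dendritic (-0.55). The authors' table gave the calls of median scaling. With the pair block, alternative NF-kB target (-0.17), immediate-early (0.14), neutrophil (-0.16), macrophage and dendritic (-0.31), eosinophil, basophil and mast cell (-0.20), and with quantile normalization as well these 5 and ribosomal protein (0.049). Where no cause is named, the cause was not tested. Over all alternatives, results of named genes kept direction and side of the threshold 1779 times, came past it 67 times and reversed 17 times. Outside the array column fit, only U30243, Tomm22, HQ446714, U41438 and Rps4y2 came past it. In that fit the correlation between arrays of 1 genotype was negative, which shrinks the error of the genotype difference. Results of lists kept direction and side of the threshold 535 times, came past it 78 times, reversed 91 times and lost the call 24 times. The 535 include the other eBayes settings and the array column, where a list's result could not change.

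The medians of the lymphoid-primed (up to 0.045) and plasma cell (up to 0.063) lists rose past 0 in some alternative, though camera's direction did not reverse. Reversals of camera's direction for lists, or of the difference for genes, were as follows, with the log2 difference or list median in parentheses. With quantile normalization, NF-kB pathway components (0.029), apoptosis (0.013), class II antigen presentation (-0.027). With median scaling, class II antigen presentation (0.067), T cell (0.16). With normexp, megakaryocyte-erythroid (0.0039), class II antigen presentation (-0.0096), heat-shock (0.066), T cell (-0.017). In the authors' deposited table, class II antigen presentation (0.067), T cell (0.16). Without the filter, apoptosis (-0.029). With the filter on all 6 arrays, megakaryocyte-erythroid (-0.066), NF-kB pathway components (0.013), ribosomal protein (-0.0022), T cell (-0.017). With array weights, NF-kB pathway components (-0.018), canonical NF-kB target (-0.0073), apoptosis (-0.019), glycolysis (-0.079), T cell (-0.20). With probe means, class II antigen presentation (0.10). With the percentile over detected probes, NF-kB pathway components (0.034), apoptosis (-0.0085), class II antigen presentation (-0.024), T cell (0.064). With the pair block, apoptosis (-0.017), class II antigen presentation (-0.032), glycolysis (-0.075). With the pair block and quantile normalization, apoptosis (0.013), class II antigen presentation (-0.027), glycolysis (-0.048). Without samples 1 and 2, cell-cycle (-0.041), apoptosis (-0.064), class II antigen presentation (-0.045), oxidative phosphorylation (-0.075), mature neutrophil (0.017), erythroblast (-0.12), endothelial and stromal (0.0058), Itgam (0.074), Rpl5 (-0.019). By fry, ribosomal protein (-0.0022), heat-shock (-0.035), T cell (0.056). With the pair block and an estimated correlation, apoptosis (-0.017), class II antigen presentation (-0.032), glycolysis (-0.075). With the pair block by fry, apoptosis (-0.017), oxidative phosphorylation (0.016), glycolysis (-0.075), ribosomal protein (-0.0022).

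Leaving out 1 array at a time took 2 list medians past 0 without reversing camera's direction. These were niche adhesion and homing (-0.21 to 0.016) and endothelial and stromal (-0.22 to 0.025). It gave these ranges for lists whose camera direction reversed and genes whose difference did. hematopoietic stem cell 0.010 to 0.070, megakaryocyte-erythroid -0.42 to 0.27, NF-kB pathway components -0.056 to 0.068, apoptosis -0.10 to 0.092, class II antigen presentation -0.28 to 0.25, mature neutrophil -0.88 to 0.55, eosinophil, basophil and mast cell -0.97 to 0.43, erythroblast -1.41 to 0.76, Map3k14 -0.21 to 0.69, Ccr7 -1.73 to 0.36, Cenpe -0.040 to 0.48, Mmp9 -1.07 to 0.45, cell-cycle -0.26 to 0.26, oxidative phosphorylation -0.36 to 0.35, glycolysis -0.35 to 0.29, ribosomal protein -0.25 to 0.37, Itgam -0.58 to 0.11, Rpl5 -0.21 to 0.39, Rpl7 -0.095 to 0.44, Sdhc -0.11 to 0.46, canonical NF-kB target -0.085 to 0.38, immediate-early -0.023 to 0.30, T cell -0.18 to 0.21, alternative NF-kB target -0.50 to 0.13, heat-shock -0.29 to 0.14, NK cell -0.82 to 0.39, macrophage and dendritic -0.77 to 0.12, Mpeg1 -0.72 to 0.015, Prg3 -2.89 to 0.15, Ccl19 -0.58 to 0.037. Those that moved by over 1.5 times without a reversal were Bcl2l1 -0.58 to -0.076, Blnk -1.01 to -0.063, Btg2 0.20 to 0.64, Btg3 0.32 to 0.90, Car2 0.26 to 0.79, Cd5l -2.96 to -0.63, Cd79a -2.29 to -0.15, Cd80 -0.69 to -0.32, Cebpa -0.98 to -0.45, Cxcl12 -2.22 to -0.28, Cxcr2 -1.23 to -0.17, Faim3 -4.27 to -0.84, Fcer1a 0.024 to 1.70, Gadd45b 0.16 to 0.59, H2-Aa 0.26 to 1.76, Ier3 0.18 to 0.45, Igj -4.46 to -1.06, Ldhb 0.23 to 0.60, B cell -1.45 to -0.033, cell-cycle inhibitor 0.093 to 0.22, granulocyte-monocyte progenitor -0.84 to -0.032, interferon response -0.41 to -0.11, lymphoid-primed progenitor -0.29 to -0.025, plasma cell -0.55 to -0.014, Ltb -0.80 to -0.30, Mpo -1.03 to -0.33, Myc -0.53 to -0.17, Notch1 -0.90 to -0.26, Nr4a2 0.024 to 1.20, Nusap1 0.27 to 0.57, Rbl1 0.23 to 0.56, Sdha 0.029 to 0.42, Stfa1 0.41 to 1.49, Tfrc 0.15 to 0.33, Tnfrsf10b 0.39 to 0.80, Tnfrsf11a 0.82 to 1.58, Usp18 -1.43 to -0.64.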

Other observations

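Several tests below were chosen after their results were seen. These are the tests of array signal, slide row and shared preparation for the resemblance of consecutive samples, those of array signal, of samples 1 and 2 and of macrophages for the granulocyte-monocyte genes, the median in splits that part all 3 pairs, and all those for B-lineage genes and immunoglobulin entries.

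NK cell markers had a median of -0.42 (9 genes; camera in limma, adjusted p = 0.111), and -0.51, -0.96 and -0.06 in the 3 pairs. Macrophage and dendritic markers had a median of -0.31 (12 of 13 lower; adjusted p = 0.075), with Itgax at -1.01 ± 0.38 (SE), Cd5l at -1.82 ± 1.16 and Mpeg1 at -0.40 ± 0.41. Cd14, the receptor that presents bacterial lipopolysaccharide, was their 1 member that read higher, at 2.04 ± 0.60. Eosinophil, basophil and mast cell markers had a median of -0.20 (14 of 18 lower; adjusted p = 0.096), with Il4 at -1.002 ± 0.40, Siglec5 at -0.40 ± 0.26, Fcer1a at 0.96 ± 0.77 and Prg3 at -1.66 ± 1.60. Of NIKaly/aly arrays, Itgax and Prg3 were well above background on 2 of 3, and Il4 and Cd5l on 1; Cd5l was so on 2 of 3 wild-type arrays. Mature neutrophil markers had a median of -0.16 (17 of 20 lower; adjusted p = 0.665), with Stfa1 at 0.83 ± 0.66, Cxcr2 at -0.69 ± 0.62, Mmp9 at -0.34 ± 0.82 and Itgam at -0.17 ± 0.43. Erythroblast markers had a median of -0.21 (adjusted p = 0.754), T cell markers 0.056 with a mean of -0.017 (adjusted p = 0.997), and endothelial and stromal markers -0.13 (adjusted p = 0.451). Immediate-early genes, which respond to handling, had a median of 0.14 (14 of 21 higher; adjusted p = 0.217), with Btg2 at 0.43 ± 0.33, Ier3 at 0.32 ± 0.26, Myc at -0.34 ± 0.30 and Nr4a2 at 0.74 ± 0.66. Heat-shock genes had a median of -0.035 (adjusted p = 0.990), and 0.51, 0.13 and -0.71 in the 3 pairs. Adjusted over the list alone with the block, 3 NK cell members passed, all lower. So did 2 macrophage and dendritic, 2 immediate-early and 1 T cell member, against 0 of each without the block. With the pairs as a block, camera called 9 lists, 7 lower and 2 higher. Beyond the 4 above these were the alternative NF-kB targets, mature neutrophil, macrophage and dendritic, and eosinophil, basophil and mast cell lists, all lower, and the immediate-early genes, higher; none was called with an estimated correlation.

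Every array's best-correlated partner was the one with the consecutive number. The best partner was the array closest in 75th percentile for only 2 of the 6. Array signal level is argued against for samples 1 and 2, whose 75th percentiles were 47.0 and 126, while that of NIKaly/aly 6 was 50.8. Among samples 3 to 6, the brighter arrays (225 and 201) and the dimmer ones (80.2 and 50.8) carry consecutive numbers, so signal level stays open there. Slide row is argued against for samples 1 to 4, all in row 1, where the lowest r between consecutive numbers exceeded the highest other r by 0.0242; samples 3 to 6 hold 0 pairs of arrays in 1 row without consecutive numbers, so row stays open there. Blood-cell RNA in samples 1 and 2 is argued against as the whole cause, because among samples 3 to 6 the difference between the wild-type arrays and that between the NIKaly/aly arrays correlated at 0.55 over genes. A shared preparation of consecutive samples may be the source and cannot be told apart from other causes, since 0 label values name a day, litter or batch.

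The granulocyte-monocyte genes read lower in all 3 pairs, and the array signal level is argued against because the highest pair median was -0.29 whichever array was brighter. Mature neutrophils in the wild-type samples are argued against as the whole cause: of the granule genes S100a8, S100a9, Camp, Ngp and Ltf, which neutrophils carry in abundance, 1 of 5 was lower in all 3 pairs. Blood-cell RNA in samples 1 and 2 is not settled as a source. Without them the median was -0.28 and 19 of 22 genes read lower, while neutrophil markers reversed to 0.017. Camera's call held at the preset correlation (adjusted p = 1.9e-05, or 3.4e-11 to 0.998 over all alternatives). The fall was thus not confined to samples 1 and 2. But the list's genes vary together (estimated correlation 0.41 with all 6 arrays), so the call cannot decide. An earlier bound, a median of -0.3 or below, was not met and was replaced after this value was seen. Macrophages or dendritic cells in the wild-type samples may be a source, as their markers read lower in samples 3 to 6 (pair medians -0.70 and -0.73), and their median of 0.0020 in samples 1 and 2, with an SD of 0.73, does not decide. A change in progenitor composition or in expression per cell with genotype is untested here.

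B cell markers other than Igj read lower in samples 1 to 4 and Igj in all 3 pairs (-6.73 in samples 5 and 6). The values leave each tested explanation open. The pairs differed (medians without Igj -0.87, -1.87 and 0.21), and leaving out 1 array could undo the difference. For a sequence variant of immunoglobulin genes, the 14 markers other than Igj had a median of -0.71 (13 lower), but -0.11 without wild type 1 and 0.031 without NIKaly/aly 4. For an equal rise of every other cell type in the wild-type samples, T cell markers had a median of 0.056 with an SD of 0.37 and a direction that changed with the processing, above the B cell median by more than that SD with all 6 arrays, but by 0.28 without wild type 1 and 0.24 without NIKaly/aly 4; NK cell (-0.42), erythroblast (-0.21) and mature neutrophil (-0.16) medians were below 0. B cells or their precursors in the wild-type samples may be a source, as may a loss of B-lineage priming in NIKaly/aly cells; the median without Igj was below 0 in 2 of 3 pairs and 0.21 in samples 5 and 6, which decides neither. Earlier bounds were replaced after their values were seen: for B cells a median above 0 in any pair, which the 0.21 met though B cells need not differ between every pair, and for the other 2 explanations the same bounds without leaving out an array.

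Of 46 tested immunoglobulin chain entries found by search terms, 41 read lower, with a median of -0.88. The median was -1.14, -0.36 and -1.51 in the 3 pairs, so unlike the markers above also below 0 in samples 5 and 6. In all 3 pairs 24 were lower and 3 (6.52%) higher. That share lies between the bounds set for and against a strain variant, which stays open for these. The search terms were corrected after a first result was seen and missed S60874, which was lower in all 3 pairs. Entries left out by the naming rule, noted after their values were seen, held the largest falls, in serum IgG2a heavy chain entries (-6.07 and -5.03). The heavy constant mu entry read -0.46, and the largest rise was in a kappa chain entry (2.92). Nnt, which carries a deletion in the C57BL/6J strain, read 1.01 higher in NIKaly/aly by 1 of its 2 probes, and the labels name no strain.

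A hypothesis set before its test was that DNA linked to the aly allele, carried along from its strain of origin, adds differing genes near Map3k14. Of the 273 tested genes within 10 Mb of Map3k14 on chromosome 11, 11 (4.03%) had an unadjusted p under 0.05 in limma with the pairs as a block, against 1132 of 15300 (7.40%) elsewhere. A one-sided Fisher's exact test gave p = 0.992, so the data do not bear the hypothesis out.

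The 6 arrays split into 3 against 3 in 10 ways, too few for a share under 0.05. No gene passed limma's adjustment in the real split or in any other (10 of 10 as many, highest other 0), with 208 genes at an unadjusted p under 0.05 in the real one. For genes at least 2-fold apart with an unadjusted p under 0.05, 6 of the 10 gave at least the real 139, and the highest other gave 1345. The 4 splits that keep samples 1 and 2 together gave 1109 to 1345, which points to a structure of the samples. For lists called by camera, 9 of 10 gave at least the real 4, with 16 as the highest other. For the size of the granulocyte-monocyte median, 5 of 10 reached the real 0.38, and the highest other was 0.85; the 4 other splits that reached it keep samples 1 and 2 together. Among the 4 splits that part all 3 pairs, fitted with the pair block, 1 of 4 reached the real 255 genes, with 95 as the highest other. For lists, 3 of 4 reached the real 9, with 13 as the highest other. For the granulocyte-monocyte median, 1 of 4 reached the real 0.38, with 0.18 as the highest other. These 4 are too few as well.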
